A study of Mus musculus with 12 samples.

How the data were processed

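RNA of natural and induced Treg was sequenced on a NextSeq 500 instrument, per the labels, in 3 libraries for each of 4 groups (nTreg and iTreg, each labelled WT or KO). The authors deposited raw counts per gene symbol, with 1 file per library and 23337 symbols in each. Per the labels, cutadapt 1.13, STAR, HTSeq 0.6.1p1, DESeq2 and the genome build mm10 were used, but the role of each tool, the order and the gene annotation are not given. The deposited counts were checked to be whole numbers with totals that differ between libraries. Totals were 6763458, 7026388 and 10845948 for nTreg WT replicates 1 to 3, 8609283, 15462894 and 9207714 for nTreg KO, 13174268, 13223102 and 11332590 for iTreg WT, and 9607726, 9660844 and 12691976 for iTreg KO. No copy of a library under another name was found.

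Genes were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test with robust dispersion, on TMM-normalised counts, in a model with a term per group over all 12 libraries (8 residual degrees of freedom). Genes were kept by edgeR's filter with a minimum count of 10 and a minimum total of 15, which left 12038. Adjusted p is Benjamini-Hochberg over these genes, and 0.05 was the threshold, with no fold limit. The comparisons were KO against WT label in nTreg, the same in iTreg, the difference of both effects (iTreg minus nTreg), and iTreg against nTreg in WT-labelled libraries. CPM values are given per library and as mean ± SD. A group without reads was set to a floor of 3 counts over the group for lower bounds of a fold; floors cover counting error only, since reads carry no molecular identifiers.

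Gene lists, 25 with at least 5 tested genes and 711 genes in all, covered ER stress branches, metabolism, T cell programmes, proliferation, cytokine responses, and markers of B, plasma, CD8, NK and myeloid cells. They were tested with camera (limma 3.58.1, preset correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation and fry, which asks only whether a list's own genes move one way, were run beside it. "Adjusted over the list alone" means that adjustment was made within a list's tested genes. Lists, comparisons, tests and most alternatives were set before the data were examined. The genes named are Syvn1, up to 10 rises and 10 falls per comparison that passed with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, up to 4 genes of smallest p of each described list, and 24 regulators, of which 1 is not reported here. For the difference, up to 5 each way were taken without the overlap rule. Predicted genes, Rik symbols and antigen receptor segments were left out. Genes outside this rule are said to be chosen after their values were seen.

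Whether replicate numbers pair libraries was checked by correlating deviations from group means. WT and KO libraries of the same number correlated at 0.497 to 0.647 in nTreg (other numbers -0.461 to -0.047) and at 0.318 to 0.669 in iTreg (others -0.55 to 0.094), but nTreg and iTreg libraries of the same number did not (-0.169 to 0.117). The fit with the replicate number as a block within each cell type (4 residual degrees of freedom) is therefore given beside the KO comparisons. Deviations cancel out within a group, so positive same-number correlations push those of other numbers down on average. The negative values are thus no separate evidence of pairs. Alternatives were edgeR's RLE size factors, no filter, a stricter filter (CPM of 5 in 3 libraries), DESeq2 1.42.0, limma voom with quality weights, the block, the 6 compared libraries alone with and without the block, a test against a 1.5-fold change, and leaving out each library in turn. Added after the data were seen were fits without the 3 libraries with Xist, without both nTreg libraries numbered 2, without both iTreg libraries numbered 3, with every library thinned to the smallest total, and with the block together with a correction for GC content and transcript length, and tests of the plasma cell markers without Derl3.

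The test was tried on simulated data. Changes of 1.5, 2 and 4-fold were recovered for 19.4%, 61.2% and 86.4% of genes in the nTreg comparison, 23.9%, 64.2% and 93.9% in iTreg, 0%, 25.4% and 65.2% for the difference, and 11.9%, 56.7% and 92.4% in WT-labelled cells. Of 11808 unchanged genes 6, 9, 2 and 6 were called, and none of 20 random lists was. The simulated genes were drawn independently and without replicate pairs. The list result therefore does not cover lists whose genes move together, such as the cell cycle list (estimated correlation 0.65 in nTreg). Coordinates are from GENCODE M21, where 20953 symbols were found, 1904 more by a synonym, and 480 were not. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Not analysed were reads, exons and splicing, since only gene counts were deposited; the Xbp1 splice form and the deleted Hrd1 exons are thus not covered. The labels give no sequencing date or batch.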

Results

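RNA was sequenced from regulatory T cells (Treg) of C57BL/6 mice aged 8 weeks, per the labels. Natural Treg (nTreg) were sorted from spleen and lymph nodes as CD4-positive cells that carry the GFP reporter of Foxp3-Cre. Induced Treg (iTreg) were made from CD4 T cells cultured with IL-2 and TGF-beta for 5 days, and GFP-positive cells were then isolated. Each cell type had 3 libraries labelled WT and 3 labelled KO, 12 in all. The WT label stands for animals with a floxed and an intact allele of Hrd1, and the KO label for animals with both alleles floxed. Both labels carry Foxp3-Cre, so WT-labelled cells may also have lost a copy of Hrd1. No group had both alleles without a floxed site. Hrd1, whose gene symbol in the files is Syvn1, is a ubiquitin ligase of the endoplasmic reticulum (ER) that marks misfolded ER proteins for degradation. The total count per library ranged from 6763458 (nTreg WT replicate 1) to 15462894 (nTreg KO replicate 2). The labels do not say whether replicates came from separate mice, so p-values measure the spread between these libraries. Xist, the RNA of the inactive X chromosome, was at 723 and 486 CPM (here without normalisation) in the nTreg libraries numbered 3 (WT and KO label), at 2035 in iTreg WT replicate 2, and at 0.232 or less in the others, while the Y-linked gene Ddx3y was absent from iTreg WT replicate 2 alone. The nTreg libraries numbered 3 thus held both Xist and Ddx3y reads (Ddx3y at 102 and 142 CPM). In iTreg, WT and KO replicate 2, which the replicate block pairs, differed in both genes (Ddx3y at 77.4 CPM in KO replicate 2). Values below are log2 fold changes with their standard error (SE) and adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with n = 3 libraries per group. All other CPM are TMM-normalised counts scaled to a common library total and are given as mean ± SD.

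The targeted gene was examined first. Syvn1 (chromosome 19, 6046576 to 6053712, plus strand, mm10; a protein-coding gene) was counted at 78.8 ± 7.33 CPM in the nTreg libraries labelled WT and 137 ± 7.94 CPM in those labelled KO, 1.74-fold higher with the KO label (log2 fold change 0.80, SE 0.17, adjusted p = 0.023, edgeR). All 3 KO-labelled nTreg libraries (145.5, 136.8 and 129.7 CPM) lay above all 3 WT-labelled ones (73.7, 87.2 and 75.5 CPM). In iTreg the level was 78.3 ± 20.5 CPM with the WT label and 63.6 ± 9.26 CPM with the KO label, a difference within the spread between libraries (log2 fold change -0.30, SE 0.17, adjusted p = 0.75). The difference of both KO effects (iTreg minus nTreg) was -1.10 (SE 0.24, adjusted p = 0.10; 0.020 with the replicate number as a block). Leaving out any 1 of the 6 nTreg libraries ended the nTreg call, with log2 fold changes from 0.76 to 0.88 and an adjusted p of up to 0.12. The nTreg value goes against the KO label. The counts cover all exons of the gene, and the sources used here do not give the floxed exons, so reads from exons outside the deleted part are included and the gene-level count does not check the label. Every direction below is therefore that of the libraries labelled KO against those labelled WT. The 3' end of Syvn1 shares 91 bp with Mrpl49, a gene on the opposite strand looked up after the Syvn1 values were seen, which did not pass the test in nTreg (log2 fold change -0.01, SE 0.12, adjusted p = 0.98).

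**Figure D1:**
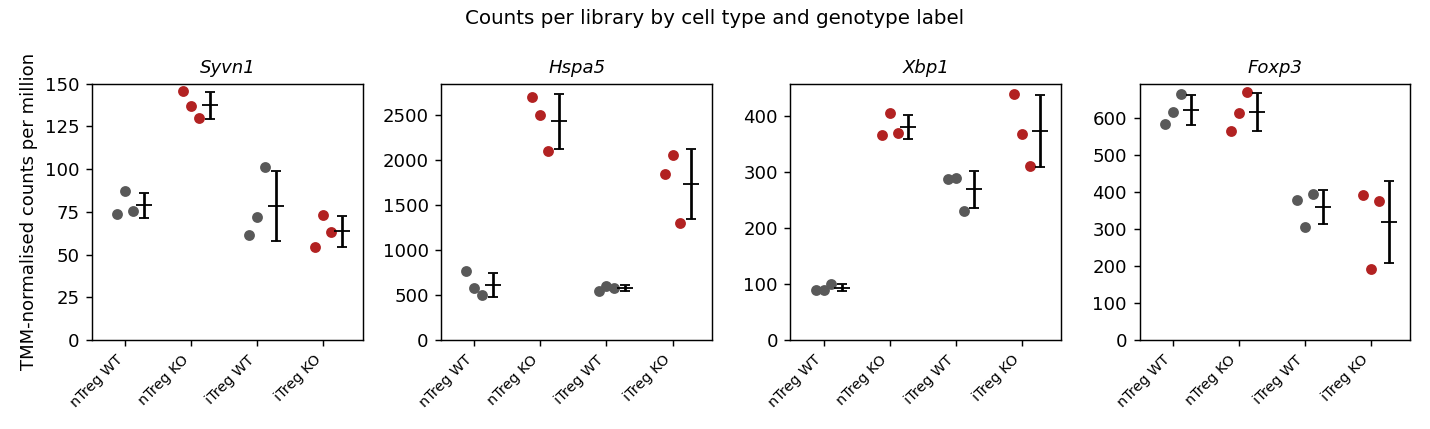
TMM-normalised CPM (vertical axes, starting at 0) of Syvn1, Hspa5, Xbp1 and Foxp3 in each library (points, n = 3 per group; grey, WT label; red, KO label), with the mean and SD as bars. Syvn1 was higher in the 3 KO-labelled nTreg libraries than in the WT-labelled ones, Hspa5 was higher with the KO label in both cell types, and Foxp3 did not pass the test with the label in either.

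Comparing KO-labelled with WT-labelled nTreg asked what floxing both Hrd1 alleles, instead of a single one, does to natural Treg. Genes of the ER stress response rose together. The target genes of the IRE1-XBP1 and ATF6 branches, which encode ER chaperones and folding enzymes, were higher in 29 of 34 tested members, and none was lower, with a median log2 fold change of 1.22 (2.33-fold). Adjusted over the list alone, 34 of 34 were higher. Pdia6, a disulfide isomerase, rose by 2.41 (SE 0.16, adjusted p = 1.1e-05), Hyou1, an ER chaperone, by 2.29 (SE 0.16, adjusted p = 1.1e-05), Sdf2l1 by 3.44 (SE 0.28, adjusted p = 3.1e-05) and Hspa5, the ER chaperone BiP, from 616 ± 135 to 2437 ± 305 CPM (log2 fold change 1.98, SE 0.19, adjusted p = 9.5e-05). Xbp1, the transcription factor of the IRE1 branch, went from 93.5 ± 6.16 to 381 ± 21 CPM (log2 fold change 2.02, SE 0.14, adjusted p = 1.1e-05).

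The PERK-ATF4-CHOP targets, which take in amino acid synthesis and transport, were higher in 22 of 32 tested members with none lower (25 adjusted over the list alone, median 1.15). Trib3, a pseudokinase induced by CHOP, rose by 4.76 (SE 0.41), Asns, asparagine synthetase, by 4.74 (SE 0.49), Slc7a5, an amino acid transporter, by 2.44 (SE 0.25) and Ddit3, which encodes CHOP itself, by 2.16 (SE 0.25), with adjusted p between 4.1e-05 and 0.00031. Of the ERAD machinery, the proteins that work with Hrd1, 5 of 27 members were higher (6 adjusted over the list alone), among them Derl3 (5.70, SE 0.32), Herpud1 (2.24, SE 0.13) and Sel1l, the partner of Hrd1 (1.07, SE 0.11), while the median member moved by 0.08. These 3 lists passed camera against other genes with the preset correlation and also with an estimated correlation (adjusted p = 0.0022, 0.0069 and 0.0069). With the replicate number as a block, the estimated-correlation adjusted p was 0.048, 0.048 and 0.091, so the ERAD call was lost. Of the called ERAD genes, Herpud1, Sel1l and Sdf2l1 also belong to the IRE1-XBP1 and ATF6 list, so the ERAD list is not a separate result. The plasma cell markers also passed (adjusted p = 0.027 with an estimated correlation, 0.076 with the block), with 1 of 8 members called, Derl3, which the ERAD list also holds (2 adjusted over the list alone and 2 with the block). The median of 0.21 was 0.42 without nTreg WT replicate 1. Without Derl3 the other 7 did not pass (adjusted p = 0.76 with an estimated correlation, 0.80 with the block; a test chosen after the list was seen to pass). Igj (immunoglobulin J chain), a plasma cell transcript singled out after its values were seen, stood at 27.9, 0.991 and 1.40 CPM in WT-labelled and 16.7, 0.819 and 1.29 CPM in KO-labelled nTreg.

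Over all genes, 304 of 12038 passed, 263 higher and 41 lower, and 1083 passed with the replicate block (645 higher, 438 lower, all 304 among them). The count was 187, 167 and 188 without nTreg WT replicate 1, 2 or 3 and 187 without nTreg KO replicate 2. Within the rule for naming genes, the largest rises were Nupr1, a stress-induced chromatin protein with no read in any WT-labelled library and thus at least 88.1-fold higher (floor of 3 counts over the group), then the glycine transporter gene Slc6a9 (6.23, SE 0.46) and Vegfa (6.06, SE 0.75). Derl3 and Atf5, a transcription factor of the ATF4 family (5.64, SE 0.22), followed, with Trib3, Asns, Slc1a4 (4.46, SE 0.43), Soat2 (3.55, SE 0.33) and Angptl6 (3.47, SE 0.61). The largest falls within that rule were smaller. Sp6 fell by 1.84 (SE 0.21), Vipr1 by 1.54 (SE 0.23) and Tmie by 1.36 (SE 0.20), followed by Fam101b, Adamtsl4, Baiap3, Bmp7, Dzip1, Art2b and Naip5, which fell by between 0.92 and 1.28. Of these 20 genes, Angptl6, Fam101b, Adamtsl4, Baiap3, Dzip1, Art2b and Naip5 lost their call when 1 library was left out (highest adjusted p 0.24, Naip5 without nTreg WT replicate 2).

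Treg identity genes did not pass camera as a group, though 24 of 33 signature genes had a negative log2 fold change. Foxp3, the factor that defines Treg, was at 621 ± 41.5 CPM with the WT label and 616 ± 51.7 CPM with the KO label (log2 fold change -0.01, SE 0.21, adjusted p = 0.99). Ctla4 (-0.03), Ikzf2 (-0.31), Nrp1 (-0.69), Tbx21 (0.02), Gata3 (-0.10), Bcl6 (-0.67), Il10 (-0.60), Mapk14 (-0.02), Prdm1 (-0.28) and Nfe2l2 (0.16) did not pass either, with adjusted p from 0.34 to 0.99. Yet each KO-labelled library lay below each WT-labelled one for Nrp1 (240, 227 and 229 against 378, 389 and 345 CPM without normalisation). The same held for Bcl6 (30.8, 42.6 and 31.6 against 49.8, 61.5 and 53.9). The spread was shared with iTreg, where KO replicate 2 lay below the other KO-labelled libraries for both genes (61.1 and 11.9 CPM). Il2ra, the IL-2 receptor alpha chain (0.47), Ifng (-1.06), Hif1a (-0.31) and Ern1, which encodes IRE1 (0.85), passed only with the replicate block (adjusted p = 0.012, 0.046, 0.035 and 0.0063, against 0.089, 0.53, 0.15 and 0.21 without it). The ER stress sensors Atf6 (0.78, SE 0.13, adjusted p = 0.0053) and Eif2ak3, which encodes PERK (0.82, SE 0.15, adjusted p = 0.0087; 0.061 without nTreg WT replicate 2), rose. Of 33 Treg signature genes, 1 was higher (Gpr83, 0.75) and 2 lower (Ecm1, -0.69, and Tigit, -0.70; the calls of Gpr83 and Tigit were lost without nTreg WT replicate 2, with adjusted p of 0.18 and 0.068), and the list did not pass camera (adjusted p = 0.061; 0.24 with an estimated correlation). With the block 5 were higher and 2 lower. The fry test gave this list an adjusted p of 0.15 for movement one way and 0.00042 for movement in either direction. Il4 and Il17a were too low to be tested.

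Other lists passed camera with the preset correlation only. Members of the cell cycle list lay higher (2 of 40 called, Cdc45 by 0.94 and E2f1 by 0.74; median 0.49). The median was 0.24 without nTreg WT replicate 2 and 0.26 without nTreg KO replicate 1, and the adjusted p of both genes was 0.13 and 0.17 without nTreg WT replicate 2. Ribosomal proteins (none of 73 called; median 0.25, or 0.12 without nTreg KO replicate 1), oxidative phosphorylation (none of 61; 0.15, or 0.074 without nTreg KO replicate 1) and cholesterol synthesis (none of 23; 0.18, or 0.11 and 0.31 without nTreg KO replicate 1 or 2) also lay higher. TCR and IL-2 signalling genes lay lower (2 of 27 called, Il2rg by -0.49 and Cd3g by -0.51; median -0.26). Both calls were lost in all 6 fits without 1 library, with adjusted p of up to 0.12 and 0.14. Naive and central T cell genes (none of 25; -0.28), Tfh genes (none of 13; -0.49), interferon response genes (none of 35; -0.22, or -0.13 and -0.15 without nTreg WT replicate 3 or KO replicate 2) and NK cell markers (none of 9; -0.58, or -0.47 with a gene at 0 taken at its bound, and -0.23 and -0.31 without nTreg WT replicate 1 or KO replicate 2) lay lower too. The replicate block changed these counts. With it, 14 cell cycle genes, 15 ribosomal protein genes such as Rpl10 (adjusted p = 0.0021), 3 oxidative phosphorylation genes such as Uqcrq (0.0083) and 1 cholesterol synthesis gene were called higher. Of the TCR and IL-2 signalling genes 8 were then lower and 2 higher, and of the interferon response genes 6 were lower, such as Usp18 (0.026), and 1 higher, Isg20 (0.00016). Lower with the block were 6 naive and central T cell genes, such as Actn1 (0.0056) and Foxo1 (0.037), 6 Tfh genes, such as Cxcr5 (0.00075), Pdcd1 (0.033) and Tox2 (0.049), and 1 NK cell marker. Without 1 library the list call ended for oxidative phosphorylation (without nTreg WT replicate 3 or KO replicate 1), cholesterol synthesis (KO replicate 1 or 3), interferon response (WT replicate 3 or KO replicate 2) and NK cell markers (WT replicate 1 or KO replicate 3), with adjusted p from 0.050 to 0.21. With an estimated correlation the adjusted p of these 9 lists was 0.39, 0.55, 0.67, 0.55, 0.21, 0.39, 0.21, 0.55 and 0.18 in that order. The lists of HIF1 and glycolysis targets, effector Treg genes, Th1, Th2 and Th17 genes, apoptosis and p53 (1 of 26 higher, Bbc3), immediate early genes, TGF-beta response, B cell markers (1 of 6 lower, Cd22, whose adjusted p was 0.069 without nTreg WT replicate 1), CD8 T cell markers and myeloid markers did not pass (adjusted p from 0.061 to 0.95). Of the lists not called, the Treg signature and the immediate early genes passed without nTreg WT replicate 1, effector Treg genes without nTreg WT replicate 1 or 2, Th1 genes without nTreg WT replicate 2 or KO replicate 1, B cell markers without nTreg KO replicate 2 and CD8 T cell markers without nTreg WT replicate 2. The median of the B cell markers was 0.46 while their test pointed down, and -0.60 without nTreg KO replicate 2. Macrophage transcripts varied between numbered pairs of nTreg libraries: Csf1r stood at 16.0, 95.3 and 30.3 CPM with the WT label and 8.34, 195 and 34.5 CPM with the KO label. Without both libraries numbered 2, 103 genes passed, all among the 304. Without the 3 libraries that carried Xist, 71 passed, all among the 304. Both of these settings were chosen after the data were seen.

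Comparing KO-labelled with WT-labelled iTreg asked the same of Treg made in culture. The ER chaperone genes were again higher. Of the IRE1-XBP1 and ATF6 targets, 13 of 34 were higher and none lower (24 adjusted over the list alone), with a median log2 fold change of 0.65 (1.57-fold). Hspa5 went from 577 ± 32.1 to 1740 ± 390 CPM (1.59, SE 0.19, adjusted p = 0.0060), Pdia6 rose by 1.53 (SE 0.16, adjusted p = 0.0041) and Hyou1 by 1.32 (SE 0.16, adjusted p = 0.0060). Over all genes 22 of 12038 passed, 20 higher and 2 lower, and 114 passed with the replicate block (81 higher, 33 lower, all 22 among them).

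Within the rule for naming genes, the 10 largest rises in iTreg were Derl3 (2.64, SE 0.28), Sdf2l1 (1.70, SE 0.26), Hspa5, Pdia6, Manf, a secreted ER stress protein, Atf5 (1.48, SE 0.18), Hyou1, Sec24d, a coat protein of vesicles leaving the ER (1.24, SE 0.19), Slc35b1 (1.14, SE 0.16) and Hsp90b1, the ER chaperone GRP94 (1.10, SE 0.19), with adjusted p from 0.0041 to 0.043. The called genes Slc7a3 (2.60) and C630004H02Rik (1.32) rose more than some of these but fell outside the ranking by that rule. The 2 genes that fell were Pglyrp1 by 1.17 (SE 0.20, adjusted p = 0.044) and Ecm1 by 0.61 (SE 0.10, adjusted p = 0.032). Of the PERK-ATF4-CHOP targets, 1 of 32 passed (Slc7a3, an amino acid transporter, 2.60, SE 0.39), 13 passed adjusted over the list alone, 8 with the block, and the median was 0.46. Ddit3 (1.25) and Asns (1.76) did not pass (adjusted p = 0.073 and 0.097; 0.057 and 0.00076 with the block). The ERAD list had 4 of 27 members higher (5 adjusted over the list alone), among them Herpud1 (1.06, SE 0.13) and Sel1l (0.80, SE 0.11). Of the called ERAD genes, Herpud1, Sel1l and Sdf2l1 are shared with the IRE1-XBP1 and ATF6 list. The IRE1-XBP1 and ATF6, ERAD and Th1 lists passed camera with an estimated correlation (adjusted p = 0.012 each; 0.087, 0.16 and 0.044 with the block), and the PERK list passed with the preset correlation only (adjusted p = 0.056 with an estimated correlation). No Th1 gene passed over all genes (6 were higher with the block), 8 were higher and 1 lower of 20 adjusted over the list alone, and the median was 0.47. Tbx21, the T-bet regulator of Th1 cells, stood at 32.2 ± 8.64 CPM with the WT label and 84.1 ± 37.7 CPM with the KO label (1.38, SE 0.27, adjusted p = 0.088; 0.0033 with the block), Tnf at 0.52 (adjusted p = 0.14; 0.030 with the block) and Ccl4 at 0.96 (adjusted p = 0.26; 0.021 with the block).

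The iTreg calls rested on few libraries. Without iTreg WT replicate 1 no gene passed edgeR's test (763 at an unadjusted p under 0.05), while DESeq2 and limma voom on all 12 libraries called 99 and 33. Without iTreg WT replicate 2 it was 1 gene, without WT replicate 3 it was 43, and without KO replicate 1, 2 or 3 it was 9, 10 or 64. Of the 16 named genes called here, each lost its call in at least 1 of these fits. When only the 6 iTreg libraries were fitted, so that the spread was not shared with nTreg, no gene passed edgeR's test (527 at an unadjusted p under 0.05). With the replicate block in the same 6 libraries 23 genes passed, 21 higher and 2 lower, 11 of them among the 22. Without the 3 libraries that carried Xist no gene passed (457 at an unadjusted p under 0.05), and without both libraries numbered 3, which lay apart on the second principal component, 75 did. With no effect, a share of 0.05 of the tested genes would on average have an unadjusted p under 0.05. The unadjusted counts above are near that share or under it, so they show no effect by themselves.

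Foxp3 in iTreg was 359 ± 46.5 CPM with the WT label and 319 ± 111 CPM with the KO label (log2 fold change -0.17, SE 0.21, adjusted p = 0.92). Ctla4 (-0.14), Il2ra (-0.07), Ikzf2 (0.11), Nrp1 (-0.47), Bcl6 (-0.40), Ifng (0.78), Ern1 (0.24), Atf6 (0.18), Eif2ak3 (0.03), Hif1a (0.15), Mapk14 (-0.07), Prdm1 (0.18) and Nfe2l2 (0.02) did not pass (adjusted p from 0.78 to 0.995). Gata3 (-0.51), Il10 (3.02) and Xbp1 (0.47) passed only with the block (adjusted p = 0.023, 0.0087 and 0.031, against 0.70, 0.45 and 0.35). The Il10 value rested on few reads, with counts of 2, 10 and 1 in the WT-labelled and 10, 68 and 6 in the KO-labelled libraries. Most of them came from KO replicate 2. Ccr8, a chemokine receptor of effector Treg, was among the 22 (0.75, SE 0.13, adjusted p = 0.043). The lists of plasma cell markers, ribosomal proteins, interferon response, Th2 and Th17 genes, oxidative phosphorylation and immediate early genes lay higher and those of the cell cycle, HIF1 and glycolysis targets and naive T cell genes lower with the preset correlation. Their adjusted p with an estimated correlation was 0.056, 0.32, 0.64, 0.089, 0.15, 0.76, 0.67, 0.64, 0.73 and 0.67 in that order. Of the plasma cell markers 1 of 8 was called, Derl3, and without it the other 7 did not pass (adjusted p = 0.52 with the preset correlation, 0.73 with an estimated one; a test chosen after the list was seen to pass). Of these 10 lists, the plasma cell markers with Derl3, ribosomal proteins and cell cycle passed in all 6 fits without 1 library. The call ended without iTreg WT replicate 1 for the interferon response, Th17, oxidative phosphorylation, immediate early, HIF1 and naive lists, without WT replicate 2 for the interferon response and HIF1 lists, and without WT replicate 3 for the Th17, immediate early and naive lists. It ended without KO replicate 1 for the naive list, without KO replicate 2 for the oxidative phosphorylation, immediate early and naive lists, and without KO replicate 3 for the interferon response, Th2, Th17, immediate early and HIF1 lists. The HIF1 median turned from -0.26 to 0.027 without iTreg WT replicate 2 and to 0.061 without KO replicate 3. The interferon response turned from 0.24 to -0.060 without KO replicate 3, immediate early genes from 0.080 to -0.039 without WT replicate 3, and oxidative phosphorylation from 0.086 to -0.049 and plasma cell markers from 0.17 to -0.082 without KO replicate 2. The other lists did not pass, but the Treg signature did without iTreg KO replicate 2, apoptosis and p53 without WT replicate 1 and B cell markers without WT replicate 3.

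The difference between the KO effects in iTreg and nTreg was tested directly. It was negative (iTreg minus nTreg) for 33 of the 35 genes that passed, and 217 passed with the replicate block (41 higher, 176 lower, all 35 among them). Atf5 differed by -4.15 (SE 0.28, adjusted p = 4.2e-05), Trib3 by -3.75 (SE 0.51), Slc1a4 by -3.98 (SE 0.53), Slc6a9 by -4.57 (SE 0.58) and Derl3 by -3.06 (SE 0.43). Xbp1 differed by -1.55 (SE 0.19) and Canx, the lectin chaperone calnexin, by -0.99 (SE 0.14), and adjusted p was 0.012 for each of these 6 after Atf5. The difference was also negative for Herpud1, by -1.18 (SE 0.18) and Vegfa by -6.13 (SE 0.90), both with adjusted p = 0.017. Nupr1 (adjusted p = 0.033) had no read in WT-labelled nTreg, 10.7 ± 4.31 CPM in KO-labelled nTreg, 52.2 ± 20.5 CPM in WT-labelled iTreg and 82.1 ± 29.9 CPM in KO-labelled iTreg. Camk4 (0.81, SE 0.14) and Gbp10 (1.69, SE 0.29) were the 2 genes with a positive difference. Hspa5 did not differ by the test (-0.39, SE 0.26, adjusted p = 0.88).

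Over the lists, the median difference was -0.62 for the IRE1-XBP1 and ATF6 targets (3 of 34 lower, 20 adjusted over the list alone, 11 with the block) and -0.70 for the PERK targets (2 of 32 lower, 15 adjusted over the list alone, 9 with the block), and both passed camera with the preset correlation only (adjusted p = 0.090 and 0.096 with an estimated correlation). The Th1 list was the only one to pass with an estimated correlation (median 0.60, 5 of 20 higher adjusted over the list alone, adjusted p = 0.023; 0.068 with the block), and no Th1 gene passed over all genes: the adjusted p of Tbx21 (1.36) was 0.30 and that of Tnf (0.68) was 0.16, or 0.022 and 0.037 with the block. Of the lists not called for the difference, Th2 genes passed in 8 of 12 fits without 1 library (any nTreg library, iTreg WT replicate 1 or iTreg KO replicate 2). Naive and central T cell genes passed without nTreg WT replicate 2, nTreg KO replicate 3, iTreg WT replicate 3 or iTreg KO replicate 2, and ribosomal proteins without nTreg WT replicate 3, nTreg KO replicate 1 or iTreg KO replicate 3. Oxidative phosphorylation passed without nTreg KO replicate 3 or iTreg KO replicate 2, immediate early genes without nTreg WT replicate 3 or KO replicate 1, plasma cell markers without nTreg WT or KO replicate 3 and NK cell markers without nTreg WT or KO replicate 2. The count of 35 genes depended on single libraries: it was 5, 13 and 1 without nTreg WT replicate 1, 2 or 3, 16, 12 and 16 without nTreg KO replicate 1, 2 or 3, 20 and 14 without iTreg WT replicate 1 or 2, and 58 and 21 without iTreg KO replicate 2 or 3. Of the 13 named genes called here, only Atf5 passed in each of these fits and in those without iTreg WT replicate 3 or iTreg KO replicate 1. Without both nTreg libraries numbered 2, and likewise without the 3 libraries that carried Xist, it was 1.

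**Figure D2:**
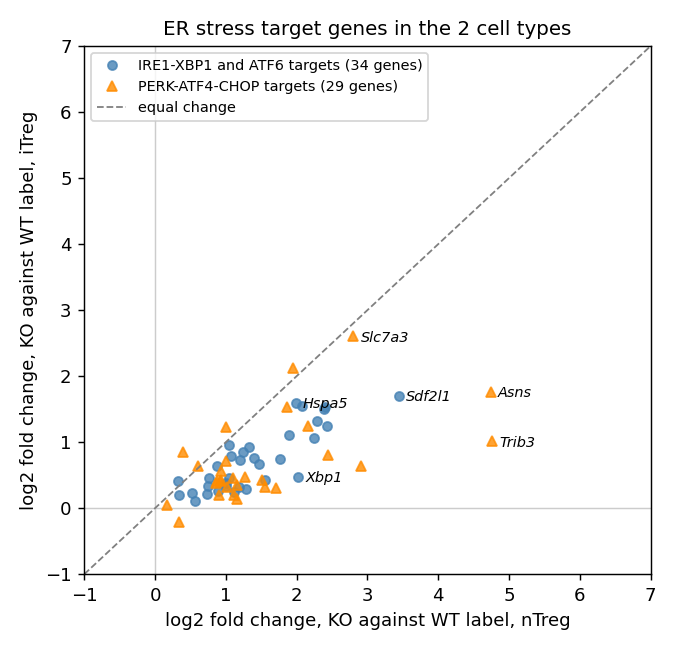
Log2 fold change of KO-labelled against WT-labelled libraries in nTreg (horizontal axis) and in iTreg (vertical axis) for each tested gene of both ER stress target lists (blue circles and orange triangles; n = 3 libraries per group), with the line of equal change dashed; 3 PERK targets with no read in 1 or more of the 4 groups are not drawn. Of the 34 IRE1-XBP1 and ATF6 targets 33 lie below the line, and of the 29 PERK targets drawn 25 do.

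Of the 22 genes called in iTreg, 20 were also called in nTreg in the same direction, 19 higher and 1 lower (Ecm1), and none in the opposite one. Independent lists of these lengths would share 0.437 genes called higher in both and 0.00681 called lower in both. The 19 included the ER chaperone and folding genes Hspa5, Hsp90b1, Pdia6, Hyou1, Sdf2l1 and Manf, the ERAD genes Sel1l, Herpud1 and Derl3, and Atf5. Of the 263 genes higher in nTreg, 228 had a positive log2 fold change in iTreg, where their median was 0.30 against 0.996 in nTreg. Across the 12038 genes, which are not independent replicates, Pearson's r between both sets of log2 fold changes was 0.188. These comparisons share no library, but the spread of each gene was estimated over all 12 libraries. A gene of small spread is thus called more readily in both, so the 2 lists of calls are not independent even without a shared effect. With the block 61 genes were shared in the same direction (53 higher, 8 lower) and 3 in opposite ones. The overlap was 0 and 1 without iTreg WT replicate 1 or 2 (763 and 670 genes at an unadjusted p under 0.05 in iTreg by edgeR, and an overlap of 55 with DESeq2 on all libraries), and 7, 9 and 40 without iTreg KO replicate 1, 2 or 3. These unadjusted counts are near the share of 0.05 expected with no effect.

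Comparing WT-labelled iTreg with WT-labelled nTreg asked how the cells differ without the KO label, with a floxed and an intact Hrd1 allele in both. The cells differed in 7850 of 12038 genes, 4187 higher and 3663 lower in iTreg. All 40 cell cycle genes were higher in iTreg, with a median log2 fold change of 3.65 (12.5-fold), among them the replication helicase gene Mcm6 (2.14, SE 0.09) and the centromere histone gene Cenpa (2.61, SE 0.12). Of the HIF1 and glycolysis targets 28 of 34 were higher (median 2.60), such as Ldha, lactate dehydrogenase (2.89, SE 0.22), and Pgk1 (3.81, SE 0.24). Cholesterol synthesis (22 of 23, median 1.42; Hmgcs1 1.98, Cyp51 2.39) and oxidative phosphorylation (53 of 61, median 0.81; Sdhd 1.17) were higher too, as were 27 of 32 PERK-ATF4-CHOP targets (median 1.28), with the serine synthesis genes Phgdh (1.90, SE 0.15) and Psat1 (1.89, SE 0.17).

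Lower in iTreg were 27 of 35 interferon response genes (median -2.37; Irf7 -4.20, Zbp1 -1.89), 20 of 25 naive and central T cell genes (median -1.63; Ccr9 -8.66, Cd27 -2.18), 19 of 27 TCR and IL-2 signalling genes (median -0.58) and 9 of 13 Tfh genes (median -1.81). Also lower were 19 of 33 Treg signature genes, of which 8 were higher (median -0.79), and 17 of 31 effector Treg genes, of which 9 were higher (median -0.93; Irf4 2.69 and Ccr8 2.52). Myeloid markers were lower in 12 of 16 (median -4.38, or -4.02 with genes at 0 taken at their bound). Each of these 12 lists passed camera with the preset correlation and none with an estimated correlation (adjusted p = 0.20 to 0.56). The preset call of the effector Treg genes ended without iTreg WT replicate 3 (adjusted p = 0.090). By that test 2 lists, the cell cycle and the Treg signature, were under 0.05 without adjustment. The fry test, which asks whether a list's own genes move one way, gave adjusted p of 0.0030 or less for all 12. The lists not named here did not pass camera, but the B cell markers (adjusted p = 0.057) did without nTreg WT replicate 2 or 3 or iTreg WT replicate 2, and the ribosomal proteins (0.057) without nTreg WT replicate 1 or iTreg WT replicate 2.

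Foxp3 was lower in iTreg (from 621 to 359 CPM; -0.79, SE 0.22, adjusted p = 0.0064), as were Ctla4 (-0.79, SE 0.21), Ikzf2, the nTreg factor Helios (-5.42, SE 0.22), Gata3 (-2.33, SE 0.26), and Il10 (-4.88, SE 0.95). So were Prdm1 (-3.89, SE 0.32), Hif1a (-0.43), Mapk14 (-0.49), Nfe2l2 (-0.36, with an adjusted p of 0.10 without iTreg WT replicate 1) and Ecm1 (-2.11). Il2ra (1.91, SE 0.13), Tbx21 (1.73, SE 0.29), Xbp1 (1.52, SE 0.14) and Eif2ak3 (0.75, SE 0.15) were higher. Syvn1 (-0.01), Nrp1 (-0.40), Bcl6 (-0.63), Ifng (0.99), Hspa5 (-0.09), Ern1 (-0.61), Atf6 (-0.15), Ddit3 (0.25) and Sel1l (-0.21) did not pass (adjusted p from 0.071 to 0.97). Of the largest rises within the rule for naming genes, Acsl6, an acyl-CoA synthetase gene (102 ± 6.02 CPM in iTreg), had no read in WT-labelled nTreg and was at least 841-fold higher. The imprinted RNA H19 was at least 582-fold, Tmeff1 507-fold, Nupr1 439-fold, Gap43 396-fold, Upp1 234-fold, Rnf180 216-fold, Lhx6 220-fold, Vldlr 198-fold and Fermt1 180-fold higher, all against a floor of 3 counts over the group. Klrg1, a receptor of mature Treg, was at least 526-fold lower, and Dtx1, a Notch pathway gene, went from 480 ± 38.9 to 1.21 ± 0.588 CPM. The other largest falls within the rule were the macrophage genes Slc40a1 (at least 487-fold), C1qc (222-fold), C1qa (196-fold), Fcna (159-fold), Csf1r, Mrc1, Cybb and C1qb. C1qa stood at 7.68, 28.6 and 12 CPM in WT-labelled nTreg, with the same order of replicates as Csf1r.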

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

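The tests for plasma cells, for library size, for GC content and length, for the spread between iTreg libraries, for the starting level in iTreg, for a single iTreg library and those of explanations for the Syvn1 value were chosen only after the result was seen; the tests of the differences, the Syvn1 level itself and the splits of the samples were set before. The following KO effects differed between iTreg and nTreg by the test of the difference (iTreg minus nTreg, log2). Negative were Atf5 (-4.15), Trib3 (-3.75), Slc1a4 (-3.98), Slc6a9 (-4.57), Derl3 (-3.06), Xbp1 (-1.55), Canx (-0.99), Herpud1 (-1.18), Vegfa (-6.13), Soat2 (-2.42) and Nupr1 (-9.18, a fitted value, since WT-labelled nTreg had no read). Positive were Camk4 (0.81) and Gbp10 (1.69). Adjusted p ranged from 4.2e-05 to 0.038. Of the lists, the median difference was -0.10 for ERAD, -0.62 for the IRE1-XBP1 and ATF6 targets, -0.70 for the PERK targets, -0.38 for the HIF1 targets, -0.23 for cholesterol synthesis, -0.75 for the cell cycle, 0.046 for effector Treg genes, 0.60 for Th1, 0.47 for Tfh, 0.33 for interferon response and 0.18 for TCR and IL-2 signalling. With an estimated correlation their adjusted p was 0.20, 0.090, 0.096, 0.63, 0.61, 0.20, 0.40, 0.023, 0.20, 0.24 and 0.20, so that Th1 alone passed. Several of these medians rested on single libraries. Without iTreg WT replicate 3 that of ERAD was -0.033 (the preset call ended), HIF1 -0.66, interferon response 0.71 and TCR and IL-2 signalling 0.32, and the calls of cholesterol synthesis (-0.15) and effector Treg genes (-0.012) ended. HIF1 was -0.22, -0.15 and -0.14 without iTreg WT replicate 1 or 2 or KO replicate 3, each of which ended its call, and -0.70 without iTreg KO replicate 2, where ERAD was -0.063. The cell cycle was -0.48 without nTreg WT replicate 2, interferon response 0.19 without iTreg WT replicate 2, and cholesterol synthesis -0.089 without nTreg KO replicate 1. Of 12 fits without 1 library, cholesterol synthesis passed in 6 and effector Treg genes in 7 (medians from -0.012 to 0.26). The calls of cholesterol synthesis ended also without nTreg WT replicate 2, nTreg KO replicate 1 or 3 and iTreg WT or KO replicate 1, and those of effector Treg genes without nTreg WT replicate 3, nTreg KO replicate 1 and iTreg KO replicate 1 or 2.

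The ER stress lists were higher in KO-labelled nTreg. Plasma or B cells in the sort, which gates on CD4 and GFP, would bring their own abundant transcripts, but 7 such transcripts outside the ER lists changed by -8.34 CPM in sum against a gain of 1821 CPM for Hspa5 (-0.458%, SE 0.58). The correction for GC content and length with the block left the median of the IRE1-XBP1 and ATF6 targets at 1.16, against 1.24 with the block alone. The transcript sum and the correction argue against plasma cells and GC or length bias as the whole cause. Thinning all libraries to the smallest total left the median at 1.22 without the block. Random thinning keeps each gene's expected share of its library, so this median could hardly change and does not test library size as a cause. Floxing of both Hrd1 alleles instead of a single one, the difference the labels name, may be the cause as a hypothesis, with the reservation on Syvn1 below.

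The ER stress response was smaller in KO-labelled iTreg than in nTreg, a weak call with an adjusted p of 0.090 with an estimated correlation. The median difference of the list stayed at -0.56 or below without any 1 library. That median is the pattern itself, so it cannot decide whether a larger spread in iTreg gave rise to it. A single iTreg library as the cause is argued against by the ratio of the iTreg to the nTreg median, at most 0.594 without any 1 of them. A higher level of the IRE1-XBP1 and ATF6 list already in WT-labelled iTreg could account for the smaller response or for part of it. KO-labelled iTreg lay at -0.34 against KO-labelled nTreg in mean log2 CPM (SE 0.16). The 95% interval over libraries was -0.95 to 0.26, so this stays open. That interval replaced a limit of 2 SE, by which the level was lower, after the value was seen. Over the genes, the higher start fell short of the smaller response (mean -0.32, SE 0.10, with 11 of 34 genes reaching it). This is the same contrast of KO-labelled iTreg with KO-labelled nTreg, taken per gene. The genes are not independent, so it adds no further evidence. The PERK targets were not put to this test. They already lay higher in WT-labelled iTreg by a median log2 fold change of 1.28. Their median difference between the KO effects was -0.70, so a higher start stays open for them too. Culture against tissue, which the design names, was not separated from cell type and is untested.

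Syvn1 counts were higher in KO-labelled nTreg. Reads of the overlapping gene Mrpl49 are argued against, since its log2 fold change was -0.012 (SE 0.12). Syvn1 may move as part of the ER stress response: 20.6% of the IRE1-XBP1 and ATF6 targets had a smaller log2 fold change in nTreg, so Syvn1 lay within their middle range, but in iTreg 0% did, outside it. An exchange of the genotype labels cannot be told apart from this, as the whole-gene value of 0.80 includes exons outside any deleted part. Exon counts would be needed.

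Other splits of the libraries were fitted in the same way. In nTreg 304 genes passed against a highest other split of 0, and 13 lists against 11; in WT-labelled cells 7850 genes against 0, and 12 lists against 14 (5 of 10 splits gave as many). With 10 splits no share can fall under 0.05. In iTreg 22 genes passed against a highest other split of 315, and 14 lists against 10, again with too few splits. The splits with 315, 123 and 32 genes parted only 1 of the 3 numbered pairs. However, 3 further splits that part only 1 pair gave 0 genes by edgeR, as did the 3 other splits that part all 3 pairs. These gene counts alone therefore do not show a structure of the iTreg libraries by replicate number. For the difference of KO effects, 8 of 100 splits gave 35 genes or more (highest 307), but the 7 others with as many all kept the real nTreg split and so held its KO effect, which leaves the gene count undecided. For the lists, 16 of 100 gave 11 or more (highest 14), 12 of them with another nTreg split, so chance is not excluded. These draws did not keep the numbered pairs together. For the overlap of 20 genes, the highest other of 100 splits gave 10, but only 11 of the 100 kept the real nTreg split. As no other nTreg split called a gene by edgeR, the remaining 89 gave 0, so these splits are too few to decide.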

How the results depend on the processing

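Fits without Xist libraries, without the nTreg libraries numbered 2 or the iTreg libraries numbered 3, thinned, or with a GC and length correction were chosen only after the result was seen; the other tests here were planned. Cause was not tested except where fewer libraries or a stricter threshold make it plain. The count of 304 genes in nTreg was 496 with DESeq2, 1068 with limma voom, 1083 with the block, and 1142 in the 6 libraries alone. It was 3746 in these with the block (1880 higher, 1866 lower), 91 against a 1.5-fold change, 167 to 216 without 1 library, 71 without the Xist libraries, 1035 with the GC and length correction and block (524 higher, 511 lower), and 103 without both libraries numbered 2. The excess of genes called higher in the main fit was thus nearly absent in the settings with 3746 and 1035 genes. The 22 genes in iTreg were 99 with DESeq2, 33 with voom, 114 with the block, 0 by edgeR in the 6 libraries alone (527 at an unadjusted p under 0.05), 23 in these with the block, 2 against a 1.5-fold change, 0 to 64 without 1 library (763 at an unadjusted p under 0.05 for the 0). They were 0 without the Xist libraries (457), 182 with the GC and length correction and block, and 75 without both libraries numbered 3. The unadjusted counts given here are near or under the share expected with no effect. The 35 genes whose effect differed were 140 with DESeq2, 103 with voom, 217 with the block, 6 against a 1.5-fold change, 1 to 58 without 1 library, 1 without the Xist libraries, 200 with the GC and length correction and block, and 1 without both nTreg libraries numbered 2. The 7850 genes in WT-labelled cells were 4489 against a 1.5-fold change and between 5874 and 8466 otherwise (8051 with the block). List counts of 13, 14, 11 and 12 were 4, 3, 1 and 0 with an estimated correlation, and in iTreg 9 to 13 without 1 library. The overlap of 20 was 55 with DESeq2, 61 with the block and 0 to 40 without 1 iTreg library. Syvn1 in nTreg was 0.76 to 0.88 without 1 library, past the threshold in none of the 6.

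Without 1 library, the median turned for 6 of the 50 list calls: in iTreg HIF1 (-0.64 to 0.061), interferon response (-0.060 to 0.43), oxidative phosphorylation (-0.049 to 0.17), immediate early (-0.039 to 0.23) and plasma cell markers (-0.082 to 0.24), and for the difference effector Treg genes (-0.012 to 0.26). It also turned for 25 of 49 lists that had not passed, such as the Treg signature for the difference (-0.052 to 0.12), and the test of Th17 genes in nTreg pointed down with the block. Of the named genes, those that turned had not passed. In nTreg, without 1 library, Foxp3 ranged from -0.076 to 0.045, Ctla4 from -0.20 to 0.15, Tbx21 from -0.062 to 0.085 (-0.014 with RLE, -0.011 with DESeq2) and Mapk14 from -0.088 to 0.032. In iTreg, Foxp3 ranged from -0.34 to 0.096, Il2ra from -0.22 to 0.056, Ctla4 from -0.26 to 0.029, Ikzf2 from -0.078 to 0.27, Ern1 from -0.074 to 0.53, Eif2ak3 from -0.11 to 0.15, Mapk14 from -0.13 to 0.022, Prdm1 from -0.22 to 0.48 and Nfe2l2 from -0.099 to 0.17. In WT-labelled cells, Syvn1 ranged from -0.24 to 0.14, Hspa5 from -0.22 to 0.093 and Ddit3 from -0.023 to 0.42. Of 169 values of named genes, 167 kept direction and side of the threshold with RLE (Gpr83 in nTreg lost its call), 158 with DESeq2 and 154 with the block. Without any 1 library, 25 of 41 named called genes stayed called in nTreg, 0 of 16 in iTreg, 1 of 13 for the difference and 48 of 49 in WT-labelled cells.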

Other observations

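The 4 lists used here were put together, and their tests chosen, only after the result was seen. Genes of the ER translocon, of glycosylation and of COPII vesicles, which carry proteins out of the ER, were higher in KO-labelled nTreg in 27 of 47 tested members (9 of the 47 also in fixed lists), with none lower and a median log2 fold change of 0.61. Cytosolic tRNA synthetase genes were higher in 11 of 20 (6 in fixed lists; median 0.66) and amino acid transporter genes in 6 of 14 (4 in fixed lists; median 0.43), with none lower in either. In iTreg 1, 0 and 1 members of these 3 lists passed.

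Part of these lists had been seen before in fixed lists or among the named genes, so the hypothesis that each class moves with the KO label was tested on the remaining members alone, with an estimated correlation. The translocon, glycosylation and COPII genes had an adjusted p of 0.0022 (38 genes, 19 higher, median 0.57), but the list was put together after the gene results were seen, so this decides nothing on the class. The tRNA synthetases did not pass (14 genes, 5 higher, median 0.28, adjusted p = 0.11), and this stays open. For the amino acid transporters all 6 called genes were among those left out, so the remaining 8 (none higher, median 0.068, adjusted p = 0.93) decide nothing on the class, which stays open. Over all members of the translocon, tRNA synthetase and transporter lists in that order, the adjusted p with an estimated correlation was 0.00098, 0.023 and 0.00015 in nTreg, 0.068, 0.21 and 0.0039 in iTreg, and 0.0096, 0.12 and 0.0020 for the difference of the KO effects. These values share the limit that the lists were chosen from the gene results.

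The iTreg libraries spread along the second principal component (4.74% of variance, against 80.4% for the first, which parted nTreg from iTreg). WT and KO replicate 3 lay at 37.4 and 26.6, and KO replicate 2 at -45.0. Genes of red pulp macrophages summed to 218, 671 and 352 CPM in nTreg WT replicates 1 to 3 and to 155, 1463 and 312 CPM in nTreg KO. In iTreg they summed to between 239 and 412 CPM although Csf1r was at 0.106 CPM or less, so part of that list is read in T cells too.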
